A study of Triticum aestivum with 6 samples.

How the data were processed

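Messenger RNA was profiled by sequencing in roots of bread wheat (Triticum aestivum, cultivar Chinese Spring), a hexaploid whose chromosomes belong to the A, B and D subgenomes. Of the 6 libraries, 3 came from roots inoculated with an arbuscular mycorrhizal fungus (AM) and 3 from non-mycorrhizal roots (NM). The series title names the fungus as Rhizophagus irregularis, a soil fungus that lives inside root cortex cells. Per the labels' protocols, RNA was extracted from about 100 mg of root per sample and read as pairs of 150 bp reads. All libraries were indexed and run together, so the labels give no sequencing batch that splits the groups. The replicates are called biological in the series' design text. The sample titles also say that a molecular signal was added to the AM samples, without saying which one.

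The deposited table holds 1 FPKM column per library, per the file headers, for 114264 IDs with 2 decimals. In FPKM, the fragments of a transcript have already been divided by its length and by the library size. TopHat2, Cufflinks, RSEM and edgeR are named in the submitters' processing notes, without versions or roles. The genome build and annotation are not given in the sources used here. Every column matched 1 sample title, and 0 columns were left unused. Read counts were not used here, so the absolute depth of each library is unknown and no counting interval was attached to an FPKM value. The relative depth was estimated from the modal ratio of low values (0.3 to 1.5 FPKM in NM replicate 1) between libraries, where 1 fragment makes a visible step. Taking NM replicate 1 as 1, these estimates were 0.871 and 0.835 for NM replicates 2 and 3, and 0.835, 0.824 and 0.920 for AM replicates 1, 2 and 3. The search was bounded and scored 2-fold steps together with the ratio itself, so a 2-fold depth difference would be read as none. FPKM steps also depend on transcript length, so whole reads were not recovered and the planned count test was not run.

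None of the 114264 IDs (0 matches) was found among the identifiers, symbols, synonyms or accessions of the 155467 genes in the reference table (assembly IWGSC CS RefSeq v2.1). The IDs are therefore used as deposited, and no gene names are given. The 37 lists of symbiosis, nutrient transport, defence, hormone and marker genes that had been fixed by description words before the data were examined had 0 members, and their set tests could not be run. For the same reason, markers of other tissues were not measured. For 100231 IDs the ID itself states a chromosome or chromosome arm. Of these, 6284 begin with TRAES3BF and carry a scaffold number and a gene number on chromosome 3B. A further 13920 begin with XLOC, the prefix that Cufflinks gives to loci, and 113 begin with EPlTAEG. Some IDs repeat one another: of 782 IDs that extend another ID by 1 character and had a value above 0 in either, 740 carried the same values in all 6 libraries. An exact 0 can be a failed estimate in this table. In each library, 12 to 25 IDs were at 0 while all the other libraries held 10 FPKM or more.

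IDs at 1 FPKM or more in at least 3 libraries were tested (64974 IDs, with 49290 left out). AM was compared with NM in limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(FPKM + 1), both groups sharing 1 estimate of the spread, without a block. P-values were adjusted by Benjamini-Hochberg over all tested IDs, and an ID was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low values. The design, this test, the filter, the rule for named IDs and most of the alternatives were fixed before the data were examined. The rule named the 2 IDs with the largest rise and the 2 with the largest fall among called IDs with no overlap between the groups and a mean of at least 1 FPKM in the higher group. It also named up to 3 members of each gene list, which gave none here. Shares of called IDs were compared between subgenomes and chromosome groups by chi-square tests on the counts. Each of 41 arms (chromosome 3B taken whole) was set against the other arms by Fisher's exact test, adjusted over 82 tests. Intervals of shares are exact binomial at 95% and cover counting error only. Genes are not independent replicates, and related copies of a gene or IDs that share reads count more than once in these tests. Single values per library were compared by two-sided exact permutation tests, whose smallest p with 3 against 3 libraries is 0.1. These used Python 3.11.15 and SciPy 1.17.1.

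The limma step was tested on simulated data with the real means and spreads of the 64974 IDs. The changed IDs were drawn only from those with a mean log2(FPKM + 1) of at least 3. That level lies above the median of tested chromosome IDs (2.67) and of tested XLOC loci (1.87). Of 100 IDs changed 2-fold, 27% were recovered, and of 100 changed 4-fold, 60%. The 90 calls included 3 false ones. Far fewer IDs were changed than the 11909 called in the real data, so these shares need not hold there or for lower IDs. The neighbour test described in the closing section was tested on shuffled calls and on planted pairs. The alternatives tried were another pseudocount, no filter, a median-ratio rescaling of the libraries, the replicate number as a block, each library left out, a stricter threshold, and a minimum fold change. The alternatives for the IDs listed at 0, for the steeply fallen IDs and for IDs with identical values were added after the data had been seen.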

Results

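Transcript levels were measured in 6 root libraries of wheat, 3 from plants inoculated with the mycorrhizal fungus (AM) and 3 from non-mycorrhizal plants (NM). The table listed 114264 IDs, of which 21673 were at 0 in all libraries. The FPKM of a library summed to between 1136829 (AM replicate 3) and 1193206 (NM replicate 2). By the steps between low values, the estimates of relative depth ran from 0.824 to 1 and overlapped between groups. The method would read a 2-fold difference as none, so how much depth differed between groups is not settled. AM libraries held more IDs at 1 FPKM or more, with 63991 ± 445 (SD, n = 3) against 60683 ± 492 (SD, n = 3) in NM. Every AM library exceeded every NM library in this number, which gave p = 0.1 in a two-sided exact permutation test, the smallest value that 3 against 3 allows.

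The groups separated more strongly than the replicates within them. Over the 64974 tested IDs, Spearman correlations ran from 0.897 to 0.935 between libraries of one group and from 0.739 to 0.820 between groups, across IDs that are not independent replicates. The first principal component carried 63.5% of the variance, with the 3 NM libraries at -101 to -119 and the 3 AM libraries at 89.9 to 150.1. AM replicate 3 lay farthest from NM on this axis.

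The study asked how the root transcriptome responds to colonization by the fungus, and the design gives 1 comparison, AM against NM. Of the tested IDs, 7272 rose in AM roots (11.2%) and 4637 fell (7.14%) at an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment. The risen IDs had a median log2 fold change of 1.27 (quartiles 0.83 and 2.05), and 1904 of them reached 2 or more. The fallen IDs had a median of -1.12 (quartiles -1.63 and -0.78), and 715 of them reached a fall of 2 or more. The median standard error of a called log2 fold change was 0.21 for risen and 0.20 for fallen IDs. In all 7272 risen and 4637 fallen IDs the 3 AM values lay entirely above or entirely below the 3 NM values. Such separation held for 38.5% of tested IDs, where chance gives 10%. A call on 3 against 3 libraries nearly requires separation, so its presence in every called ID is no separate support for the calls. Without NM replicate 1 the counts were 4240 risen and 2283 fallen, without NM replicate 2 they were 4089 and 2124, and without AM replicate 3 they were 4920 and 2983, all under the counts from 6 libraries by over 1.5 times except the 4920.

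**Figure D1:**
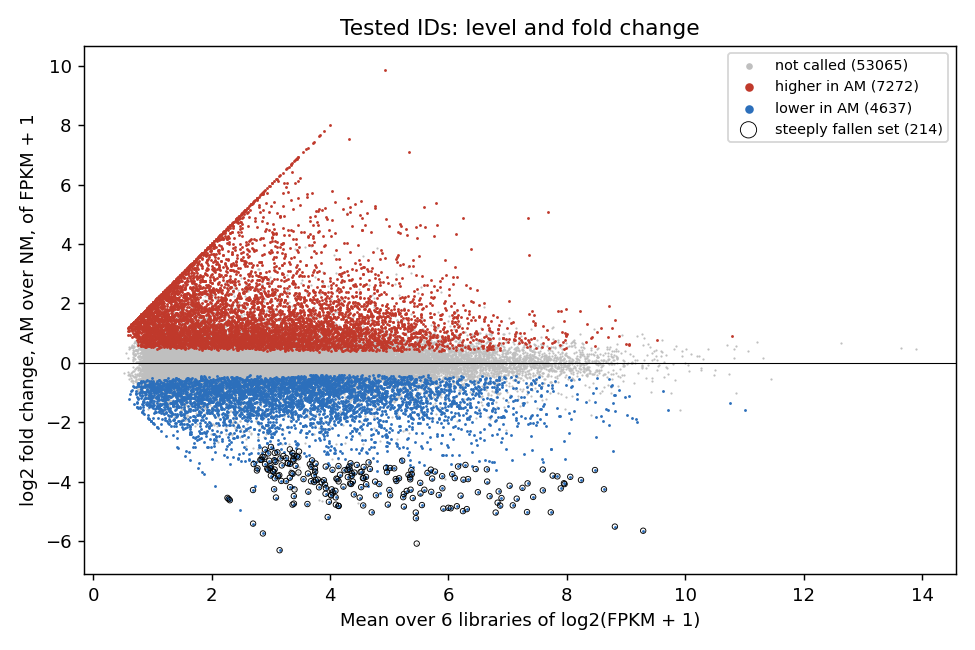
Each point is a tested ID, with its mean log2(FPKM + 1) over the 6 libraries on the x axis and its log2 fold change of AM over NM on the y axis; red IDs were called higher (7272), blue IDs lower (4637), grey IDs were not called, and black circles mark the 214 IDs of the steeply fallen set. The red edge running up from the lower left is formed by IDs at or near 0 in NM, and the circled IDs lie at the bottom across a wide range of levels.

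Among called IDs, the 2 largest fitted rises and the 2 largest fitted falls were in IDs listed at 0 in every library of one group. TRAES3BF058900100CFD_g, an ID of chromosome 3B, was listed at 0 in all 3 NM libraries and at 571.86, 1182.64 and 1166.66 FPKM in AM replicates 1, 2 and 3 (adjusted p = 8.57e-05, limma). Traes_5DL_5C26BBD7C, an ID of arm 5DL, was listed at 0 in all 3 NM libraries and at 69.86, 475.08 and 512.34 FPKM in AM (adjusted p = 0.00144, limma). In the other direction, XLOC_077824 was listed at 84.99, 60.09 and 91.71 FPKM in NM replicates 1, 2 and 3 and at 0 in every AM library (adjusted p = 8.57e-05, limma). Traes_4BL_F6C3B5069, an ID of arm 4BL, was listed at 47.5, 76.43 and 39.14 FPKM in NM and at 0 in every AM library (adjusted p = 0.000212, limma). No fold is given for these IDs because a listed 0 has no known detection limit without counts. The fallen pair belongs to 3 IDs at 0 in every AM library and at 20 FPKM or more in every NM library, where other choices of 3 libraries against 3 gave up to 5. The table pairs no ID with a gene name, so what these genes encode is not given here.

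Some IDs were listed at 0 in every NM library and had values above 0 in every AM library. There were 254 IDs at 0 in every NM library and at 5 FPKM or more in every AM library, and all 254 were called higher. Their selection already separated the groups, so these calls are no separate support. The reverse pattern, 0 in every AM library and 5 FPKM or more in every NM library, held for 13 IDs, and the other choices of 3 libraries against 3 gave 4 to 15 such IDs. By the chromosome in the ID, 55 of the 254 belonged to the A, 48 to the B and 63 to the D subgenome, and 88 were XLOC loci. Their median level was 13.2 FPKM in AM replicate 1, 20.7 in replicate 2 and 26.0 in replicate 3. At 20 FPKM or more in every AM library the count was 70 IDs, against 3 in the reverse direction. The 254 IDs together accounted for 10158 ± 3477 FPKM (SD, n = 3) in AM.

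The steepest falls of abundant transcripts were examined as a set. The set was defined after the data were seen as tested IDs at 10 FPKM or more in every NM library, with an NM mean of 20 FPKM or more and at most a 16th of that mean in both AM replicates 1 and 3. It held 214 IDs, of which 205 were called lower, and their median NM mean was 79.1 FPKM. By the chromosome in the ID, they comprised 64 IDs on the A, 62 on the B and 66 on the D subgenome, and 22 XLOC loci. Together they made up 4.13% ± 0.55 (SD, n = 3) of the summed FPKM in NM and 0.122%, 0.696% and 0.0871% in AM replicates 1, 2 and 3, where the definition capped the values of replicates 1 and 3. In AM replicate 1 the set lay at a median of 2.98% of the NM mean (quartiles 1.77% and 4.17%), and in AM replicate 3 at 1.83% (quartiles 0.933% and 3.01%). In AM replicate 2, which was not used to define the set, the median was 18.2% (quartiles 13.9% and 22.9%). Because the definition required low values in AM replicates 1 and 3 only, part of this gap is built into the set. Among IDs at 20 FPKM or more in all NM libraries, the mean of AM replicates 1 and 3 lay 2 to 4-fold below the NM mean in 838 IDs, 4 to 8-fold in 281, 8 to 16-fold in 99, 16 to 32-fold in 95 and 32-fold or more in 125. In these classes the median level in AM replicate 2 was 47.5%, 33.9%, 24.1%, 21.9% and 16.2% of the NM mean, against 38.1%, 19.6%, 8.85%, 4.20% and 1.94% for the mean of AM replicates 1 and 3, which formed the classes. For a fall of 8 to 16-fold, the library left out of the classes lay at a median of 2.79 times the mean of the other AM libraries for replicate 2, 0.367 times for replicate 1 and 0.207 times for replicate 3. With AM replicate 2 in the definition in place of replicate 1 or of replicate 3, the set held 18 or 14 IDs.

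**Figure D2:**
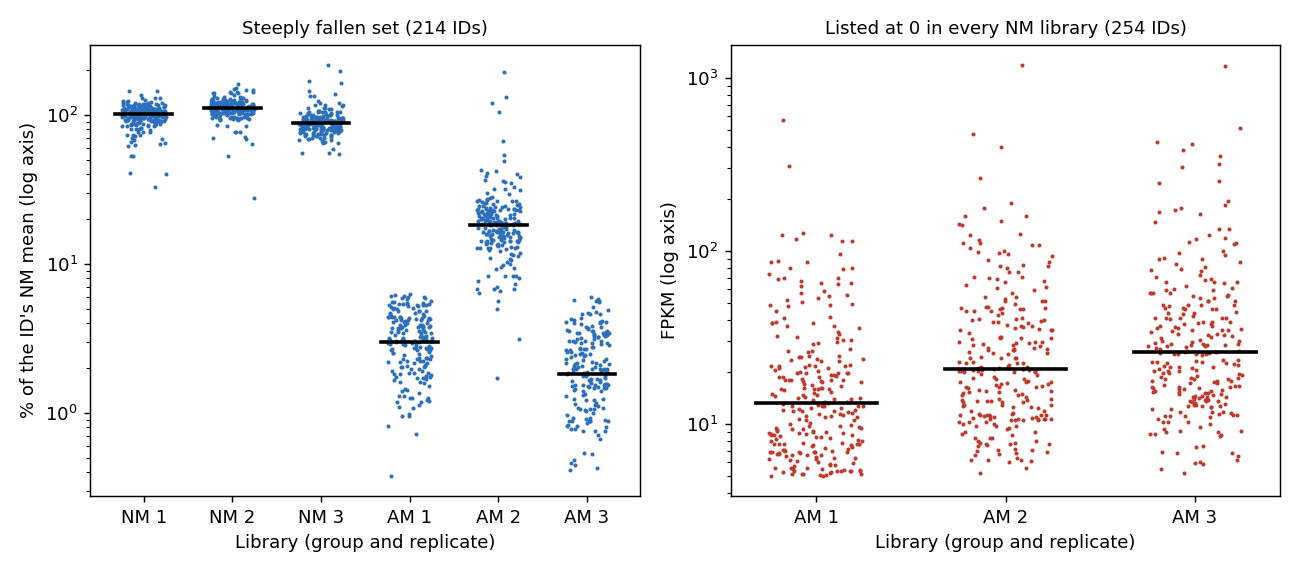
Left, the level of each of the 214 steeply fallen IDs as a percentage of its own NM mean in each library, on a log axis; the 21, 6 and 25 IDs at 0 in AM replicates 1, 2 and 3 are not drawn. Right, the FPKM of the 254 IDs listed at 0 in every NM library, in the 3 AM libraries, on a log axis; points are IDs and black lines are medians (18.2% in AM replicate 2 against 2.98% and 1.83% in the other AM libraries on the left).

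The A, B and D subgenomes took part in similar shares. IDs that rose made up 11.1% of the tested A IDs (1944 of 17466), 11.3% of the B IDs (2103 of 18635) and 11.1% of the D IDs (1999 of 17993), with a chi-square p of 0.844. IDs that fell made up 7.44%, 7.57% and 7.72% of the A, B and D IDs (chi-square p = 0.603). The exact 95% intervals of the risen shares were 10.7% to 11.6% for A, 10.8% to 11.7% for B and 10.7% to 11.6% for D. The A subgenome contributed 31.5% ± 0.36 (SD, n = 3) of the summed FPKM of chromosome IDs in AM and 30.8% ± 0.07 (SD, n = 3) in NM, p = 0.1 in the exact permutation test. The B and D shares differed by -0.366 and -0.352 percentage points, AM minus NM (exact permutation p = 0.6 and 0.4).

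Chromosomes differed more than subgenomes did. The risen share was highest on the group 2 chromosomes, with 13.4% of 9842 tested IDs (interval 12.7% to 14.1%), and lowest on group 4 with 9.94% of 7749 (interval 9.28% to 10.6%), and it differed over the 7 groups with a chi-square p of 1.38e-13. All 6 arms of group 2 lay between 12.8% and 14.1%, and of these 2AL and 2DL passed the adjusted test against the other arms (adjusted Fisher's exact p = 0.00145 and 0.0228). Chromosome 3B (13.6% of 3202 IDs, adjusted Fisher's exact p = 0.000358) and arm 5DL (13.2% of 2147, adjusted p = 0.0240) also lay above the rest. Arms 3DS (5.77% of 919, adjusted Fisher's exact p = 1.46e-06), 7BS (6.66% of 826, adjusted p = 0.000358), 4DL (8.25% of 1637, adjusted p = 0.00151) and 7BL (8.50% of 1200, adjusted p = 0.0240) lay below. These 8 arms also passed when IDs were compared within 10 classes of mean level. IDs with identical values, which occur on 3B, were each counted in the arm tests. The fallen share varied less, from 6.65% on group 7 to 8.22% on group 1 (chi-square p = 0.00213), and arm 3DL alone passed the adjusted test, with 5.52% of 1449 (adjusted Fisher's exact p = 0.0240), but not within level classes (adjusted p = 0.0689).

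**Figure D3:**
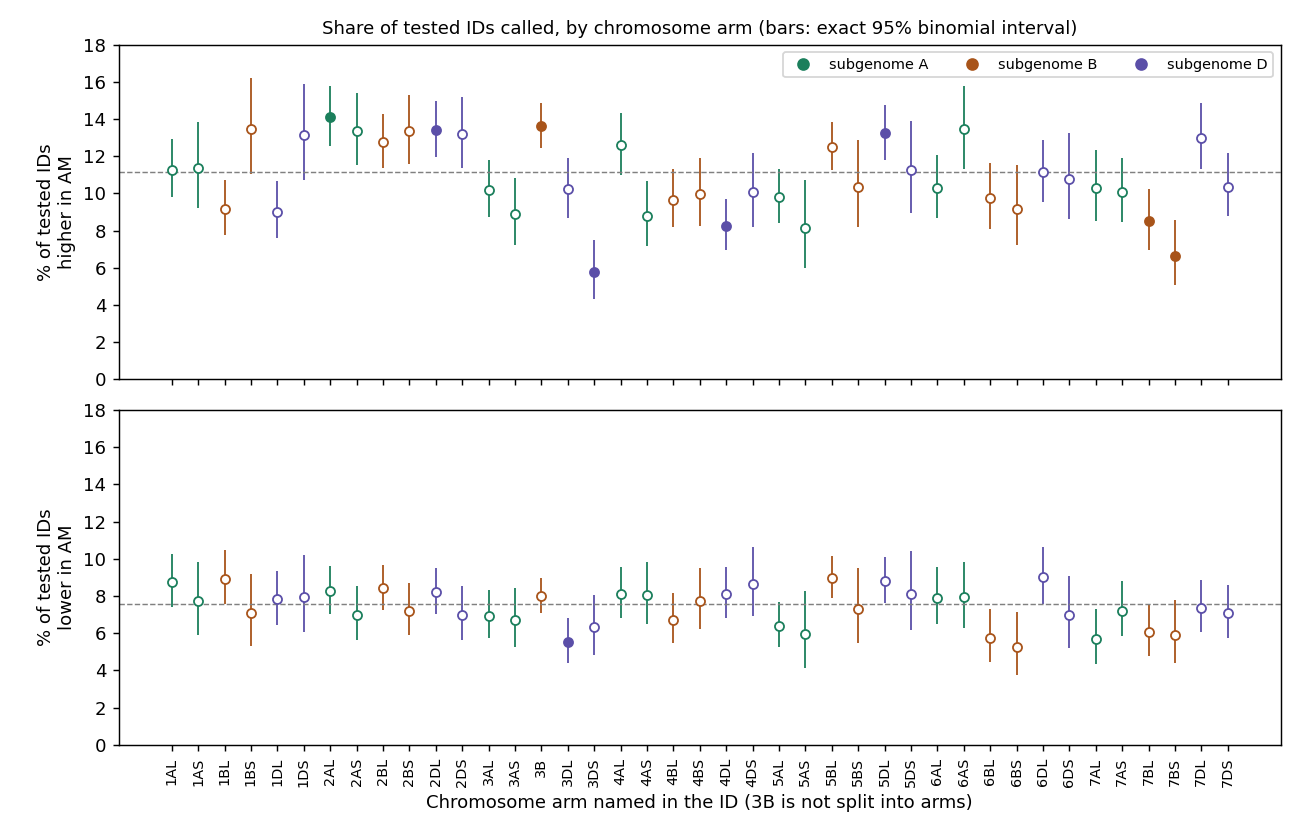
Share of tested IDs called higher (top) or lower (bottom) in AM for each chromosome arm named in the ID, coloured by subgenome. Bars are exact 95% binomial intervals, and filled points mark arms with an adjusted Fisher's exact p under 0.05. The dashed line is the share over all tested chromosome IDs pooled. Group 2 arms and 3B sit above the line in the top panel, and 3DS (5.77%) and 7BS (6.66%) sit lowest.

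XLOC loci rose as often as IDs with a chromosome but fell less often. Of 10853 tested XLOC loci, 11.3% rose and 4.97% fell, against 11.2% and 7.58% of 54094 chromosome IDs. The fallen shares differed (Fisher's exact p = 1.07e-23), and they did so within classes of mean level (p = 4.42e-05), while the risen shares did not pass (Fisher's exact p = 0.802). XLOC loci had a lower median level, 1.87 against 2.67 on the log2(FPKM + 1) scale. Of 27 tested EPlTAEG IDs, 4 rose and 0 fell in limma.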

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

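The settings for the IDs listed at 0 in NM, for the steeply fallen IDs and for identical IDs were chosen after the results were seen, and the others before. No setting that was run reversed a result. With the replicate number as a replicate block the counts were 6323 risen and 4094 fallen; every library's deviations correlated best with those of its own number (0.124, 0.0708 and 0.0437), but only 1 of the 3 correlations passed 0.1, so this is a hint from the data and not a pairing. At an adjusted p under 0.01 the counts were 3166 and 1626, and with an absolute log2 fold change of at least 1 they were 4669 and 2673. Leaving out 1 library at a time gave 4089 to 6065 risen and 2124 to 4071 fallen IDs. Pseudocount 0.1, no filter and median-ratio rescaling kept both counts within 1.5 times. Counting identical IDs once or leaving out the steeply fallen set did so too, but only dropped IDs from the main calls. Neither was a new fit, and leaving out the set (7272 risen, 4432 fallen) does not test whether it shifts the other values. Rescaling moved the median log2 fold change of the tested IDs from 0.05 to 0.02 and the risen share of the calls from 61.1% to 57.3%. All 40 alternative fits of the 4 named IDs stayed called in the same direction. The 254 IDs listed at 0 in NM became 624, 148 or 70 at 1, 10 or 20 FPKM, and 286 to 371 with 1 library left out. The 214 steeply fallen IDs became 322 or 108 for an 8-fold or 32-fold fall, and 18 or 14 with AM replicate 1 or 3 kept out of the definition in place of replicate 2. Some of these settings used fewer libraries or a stricter rule, and the cause of the shifts was not tested. The gene list tests had no members and the count test had no counts, so neither was run. Depth limits the low IDs, where FPKM moves in steps of 1 fragment.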

Other observations

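The tests of chance, of a single source of RNA (the fungus included) and of failed estimates were chosen after the results had been seen. So were the test of arms of the same name and the XLOC and chromosome 3B comparisons. The tests of carry-over and of neighbours on 3B were set before their results were seen. Among IDs at 5 FPKM or more in every AM library, XLOC loci were more often listed at 0 in every NM library. The comparison was not made within classes of mean level, although tested XLOC loci had a lower median level than chromosome IDs. Of 2686 XLOC loci at 5 FPKM or more in every AM library, 88 were listed at 0 in every NM library (3.28%, exact 95% interval 2.64% to 4.02%), against 166 of 25580 IDs with a chromosome (0.649%, interval 0.554% to 0.755%; Fisher's exact p = 2.99e-28). The shares of A, B and D IDs in this set, 0.671%, 0.541% and 0.741%, did not pass a chi-square test (p = 0.248). On chromosome 3B the risen share was 13.7% among 2774 TRAES3BF IDs (exact 95% interval 12.4% to 15.0%) and 13.3% among 428 Traes_3B IDs (10.2% to 16.9%), against 9.69% of 2581 IDs on 3A (8.57% to 10.9%) and 8.49% of 2368 on 3D (7.40% to 9.68%); these shares were not tested against each other.

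Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many calls as 11909, and the highest other split gave 25. With 10 splits the share cannot fall under 0.05.

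The 214 steeply fallen IDs lay at a median of 18.2% of their NM level in AM replicate 2, against 2.98% and 1.83% in AM replicates 1 and 3, where the definition capped them. One source of RNA in different amounts would hold them near 1 fraction in AM replicate 2. There, 82.7% lay within 2-fold of the median, but so did 88.8% of the 1218 IDs with smaller falls, of 2 to 16-fold, around their own median. In classes of 2 to 16-fold falls formed without AM replicate 1 or 3, 64.6% and 62.1% lay within 2-fold in the library left out. Because smaller falls were as tight in AM replicate 2, the share does not decide for a single source. Added RNA like that of NM would also lift smaller falls there, so their tightness does not count against a single source. Material of the NM libraries carried over into AM replicate 2 would leave every abundant NM transcript at about that fraction or more, and of 8940 IDs at 20 FPKM or more in all NM libraries, 3 lay above 0 and below 4.54% of their NM mean, the bound set in advance, against 145 and 192 in AM replicates 1 and 3. A further 20 of the 8940 were listed at 0 in AM replicate 2, which carry-over also forbids unless they are failed estimates; 22 and 42 were at 0 in AM replicates 1 and 3, and 3 were at 0 in all AM libraries, where other splits gave up to 5. The 3 IDs above 0 and below the bound met the prediction of carry-over set in advance, and the 20 at 0 did not enter it. Carry-over therefore stays open, as does a single source. A response of these IDs to the fungus that was weaker in AM replicate 2 was not tested and also stays open. The 254 IDs listed at 0 in every NM library were not lowest in AM replicate 2. Their medians were 13.2, 20.7 and 26.0 FPKM in AM replicates 1, 2 and 3. Carry-over of about 18.2% would lower these IDs by less than AM replicates 1 and 3 differed from each other. These medians therefore test neither carry-over nor a weaker response of the fallen IDs.

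The 254 IDs listed at 0 in every NM library could be failed estimates, but other choices of 3 libraries against 3 gave at most 15 such IDs, far below 254. Reads of the fungus counted on wheat loci may be another explanation. One such source, if its own expression were the same in each library, would hold its transcripts in 1 ratio, with scatter from counting alone. The AM libraries are biological replicates, so the expression of the fungus may differ between them. The robust SD of the log2 ratio of AM replicate 3 to replicate 1 was 2.15 times that of unchanged IDs of the same FPKM (95% bootstrap interval 1.86 to 2.59), and also 2.15 times among the 61 IDs with an AM mean of 40 FPKM or more, but FPKM does not give the fragments behind a value, and some of these IDs move in shared steps of few fragments. The scatter therefore does not decide, and reads of the fungus and a response of root genes to colonization both stay open.

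Adjacent genes on chromosome 3B, by the numbers in their IDs, may respond together. Both members rose in 33 of 1134 adjacent pairs, against a mean of 21.2 and a highest value of 38 in 10000 shuffles (permutation p = 0.0063), which missed the bound set in advance of exceeding every shuffle. Both fell in 18 pairs, against a mean of 7.19 and a highest value of 19 (permutation p = 0.0004), which missed the same bound. Some adjacent pairs repeat with identical values under other scaffold numbers. The shuffles moved each copy on its own, so these p-values may be too small. Among pairs whose deviations within groups correlated at 0.5 or less, 12 rose together against a shuffled mean of 15.5 (permutation p = 0.855) and 6 fell together against a mean of 4.45 (permutation p = 0.288), so no excess passed there. Reads shared between neighbouring copies are a candidate explanation, and neighbours with a common response are not told from it by these values.

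Homoeologous arms carry related genes, so risen shares were compared, as a hypothesis, between arms of the same name. Whether each pair of the same name is homoeologous along its length was not checked. The correlations therefore describe arms paired by name and do not settle the relation of homoeologous arms. Across 14 arm pairs the shares on A and D arms correlated at r = 0.32 (permutation p = 0.264; rho = 0.31, p = 0.282; r = 0.22 without the 2 arms farthest from the median). Across 12 pairs B and D gave r = 0.64 (permutation p = 0.0251; rho = 0.66, p = 0.0232; r = 0.51 without 2 arms) and A and B gave r = 0.33 (permutation p = 0.291; rho = 0.17, p = 0.605; r = 0.24 without 2 arms). After Benjamini-Hochberg adjustment over 6 correlations the smallest p was 0.150, so no relation between arms of the same name passed.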
